A study of Homo sapiens with 9 samples.

How the data were processed

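Total RNA was measured in 9 samples of the H3122 line, 3 each of Parental, PF1066R and X376R cells, on Illumina bead arrays. Per the labels' protocols, RNA was extracted with Trizol, cleaned with RNeasy columns and DNase I and checked on a Bioanalyser, and biotinylated cRNA was made with the Ambion MessageAmp kit. The deposited table of signals holds 1 intensity per probe and array on a linear scale. Its lowest value of 60.4 gives no sign that background was subtracted from the summarized signals, and whether it was removed from single beads is not known. The scanner software and the summarization of beads are not given in the sources used here. A second deposited table holds log2 values that the authors normalized, which by their distribution are quantile-normalized signals, and R 2.15 is listed in the submitters' processing notes. In that log2 table the replicate 1 values of each line seem to be the mean of 2 quantile-normalized arrays, of which 1 is in the table of signals: 95.1%, 94.7% and 94.8% of values lie within 1e-06 of what such a mean would give. That is inferred from the values, and the sources used here do not mention a second array. The table of signals was therefore used for every test and the log2 table only as an alternative. Whether cells were kept with inhibitor before lysis, and whether the samples of a line were grown apart, is not given in the sources used here.

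Of 47323 probes 1 had no value. A table of probe names gave 1 gene symbol for 30112 probes, several for 8 and none for 17202, and 30073 of the named probes had a gene in the GRCh38.p14 reference table, which was used for names and neighbours alone. The comparisons, threshold, gene lists, naming rule and the first set of alternatives were chosen before the data were examined. The plan took background and filter from a detection p, which the table of signals lacks, and it names no control probes. The plan's stated substitute was used: limma normexp background correction with an offset of 50, quantile normalization and log2. In place of a detection p, a probe counted as above background where its signal exceeded the highest of 92 external control probes on that array, and a probe had to do so on at least 3 of 9 arrays. The tables do not name these probes, whose IDs share a range and which were taken for external controls from knowledge of the platform. That limit was chosen after the lack of a detection p was seen. Between 35.9% and 65.7% of probes lay above background on an array, and 26814 passed, 18575 of them with a gene name and 8239 without. The probe with the highest mean log2 value stood for a gene, which gave 13769 genes, 3662 of them with several passing probes.

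A limma model with 1 mean per line was fitted to all 9 arrays, with moderated t tests for PF1066R minus Parental, X376R minus Parental and X376R minus PF1066R. Benjamini-Hochberg adjusted p under 0.05 within a comparison was the threshold. No replicate block was used, since nothing in the labels says what a replicate number marks. The median standard error of a log2 change was 0.120, with 6 residual and 10.6 prior degrees of freedom. Genes in both resistant lines were counted by direction, beside the overlap of independent lists and 100 simulated sets of unchanged groups against the same Parental arrays. A bound on a fold sets the bright line's mean log2 value against the mean, over the dim line's arrays, of the higher of 2 values: the lowest signal among probes above background and the probe's own.

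The 39 gene lists were written from general knowledge of pathways, cell types and drug response. Of 784 members written 625 were measured, and 38 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. In fry, 1 p asks whether a list moves on balance in 1 direction and the other whether its members change in either direction, and neither compares the list with other genes. Fry's directional p passed for 29, 23 and 26 lists.

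The text names genes by a rule: 10 receptors, adaptors and fusion partners in every comparison, the 12 highest and 12 lowest changes of each resistant line, the 8 highest and 8 lowest between the lines and in both lines, 6 of opposite direction, and up to 4 members of each list by size of change. Highest and lowest were taken among genes past the threshold whose 3 arrays of one line all lay above the 3 of the other, and names made of locus or reading frame numbers were passed over. Of 276 genes the rule gives, 125 are left out of the text. A further 8 genes from outside the rule, CDH1 and 7 fibroblast transcripts, were chosen after the changes were seen.

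Background correction, normalization, the fit and the list test were tested on simulated data with 13769 genes and the spread of the Parental arrays. The filter and the choice of probe were taken from the real data. Simulated noise was independent between genes, so the list test was not tried under correlation between genes. Of genes given a true log2 change of 0.5, 1 and 2, 20.9%, 53.7% and 80.3% were called in PF1066R against Parental, 17.9%, 37.3% and 78.8% in X376R against Parental and 13.4%, 35.8% and 69.7% between the resistant lines. Among unchanged genes 6, 5 and 2 were called, a raised list was found each time, and 0 random lists were called. Background correction with an offset shrinks changes of dim genes, so folds of such genes are low estimates.

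Alternatives covered background correction, normalization between arrays, the authors' log2 values, the filter, the choice of probe, the replicate number, the samples in the fit, the variance model, the threshold, array brightness, the list test and each array left out. Probes with no gene name were tested as probes and enter no gene count. Tests were run in R 4.3.3 with limma 3.58.1, and figures drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.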

Results

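Total RNA from H3122, a human lung adenocarcinoma line that carries an EML4-ALK fusion, was hybridised to 9 Illumina bead arrays. The cells came as 3 isogenic lines with 3 arrays each. Parental cells are sensitive to the ALK inhibitors crizotinib (named PF1066 in the labels) and X-376, PF1066R cells had been made resistant to crizotinib, and X376R cells to X-376. Signals were read for 47322 probes, of which 35.9% to 65.7% lay above background on a single array, and 13769 genes were tested. Mean probe signal was 254 ± 37.9 units (SD, n = 3) in Parental, 201 ± 30.3 in PF1066R and 173 ± 9.09 in X376R, so the resistant lines' arrays were on the whole dimmer. After normalization, arrays of a group correlated with r of 0.980 to 0.989 over the tested genes and arrays of different groups with r of 0.929 to 0.963. The first principal component held 50.3% of the variance and the second 23.3%. With 3 arrays a group, the number of arrays limits the precision. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each drug is represented by a single resistant line, so traits of that line cannot be told apart from resistance to its drug. Whether cells were kept with inhibitor before lysis is not given in the sources used here. Changes from Parental, those of MAPK feedback genes among them, may therefore reflect inhibitor present at lysis or resistance, which cannot be told apart. Gene lists were tested with camera, which compares a list's members with all other genes tested. Below, gene values are log2 changes ± SE from limma with n = 3 arrays a group, and adjusted p is by Benjamini-Hochberg over all genes tested.

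**Figure D1:**
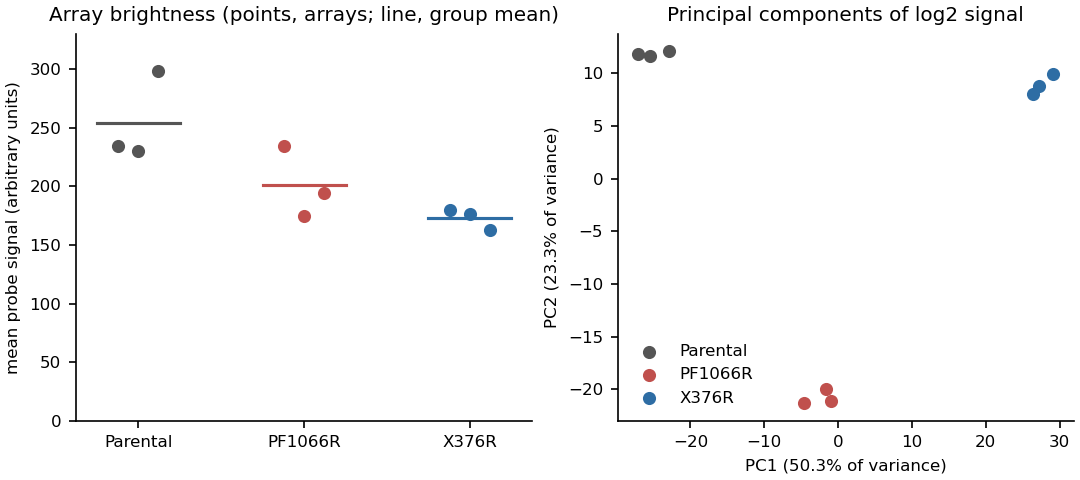
Left, mean probe signal of each array (points, arbitrary units) with the group mean (line), n = 3 arrays a group. Right, the arrays on the first 2 principal components of log2 signal over 13769 genes, where the 3 lines stand apart.

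The first comparison asked how expression in the crizotinib-resistant line differed from that in its sensitive parent. ALK, the kinase of the fusion, was 3.97-fold higher in PF1066R (1.99 ± 0.12, adjusted p = 5.4e-09), while EML4, its partner, gave 0.01 ± 0.13 (adjusted p = 0.969). Which part of ALK or EML4 each probe reads is not given in the sources used here, so fusion and unfused transcripts are not told apart. The EML4 value therefore does not show whether the fusion transcript changed. Interferon-stimulated genes and genes of cholesterol synthesis rose with it, and feedback genes of MAPK signalling and targets of ATF4, a transcription factor of the amino acid response, fell. In all, 2539 genes passed an adjusted p of 0.05, 1250 higher and 1289 lower in PF1066R, and 235 of them differed by at least 2-fold (96 higher, 139 lower).

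The secreted ribonuclease RNASE1 was 7.61-fold higher (2.93 ± 0.15), the mucosal secretory protein MSMB 7.15-fold (2.84 ± 0.14) and the aldehyde dehydrogenase ALDH3A1 6.88-fold (2.78 ± 0.12). INSIG1, which holds sterol-regulated transcription factors in the endoplasmic reticulum, rose 5.89-fold (2.56 ± 0.13), AKR1C2, a reductase of steroids and reactive carbonyls, 5.34-fold (2.42 ± 0.12), and ACSS2, which makes acetyl-CoA from acetate, 5.23-fold (2.39 ± 0.15). SCD, the desaturase that makes monounsaturated fatty acids, rose 4.30-fold (2.11 ± 0.12) and CYP1A1, a monooxygenase induced by the aryl hydrocarbon receptor, 4.02-fold (2.01 ± 0.15). The antiviral genes IFI6, MX1 and IFIT1 rose 4.49-fold, 4.21-fold and 3.97-fold. SERPINE2, a secreted inhibitor of serine proteases, was 8.19-fold lower (-3.03 ± 0.13), the acute-phase protease inhibitor SERPINA3 7.13-fold (-2.83 ± 0.16), and the trypsin PRSS3 5.74-fold (-2.52 ± 0.12, above background on 2 of 3 PF1066R arrays). MAT2A, which makes the methyl donor S-adenosylmethionine, fell 4.99-fold and ODC1, the first enzyme of polyamine synthesis, 4.61-fold. IGFBP3, a binding protein for insulin-like growth factors, fell 4.93-fold (-2.30 ± 0.17), and the chromatin protein HMGA1 4.28-fold (-2.10 ± 0.12). The microtubule-destabilising protein STMN3 fell 4.95-fold, PHLDA1, a gene induced by MAPK signalling, 4.71-fold, ERRFI1, a feedback inhibitor of EGFR, 4.26-fold, the integrin subunit ITGB5 4.24-fold and the gel-forming mucin MUC2 3.98-fold. The naming rule required all 3 arrays of one line to lie above all 3 of the other for each of these genes.

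Among interferon response genes, 17 of 27 measured members rose, 1 fell and 9 did not pass (19 and 1 adjusted over the list alone), and camera's adjusted p was 1.24e-13. IFI6 (2.17 ± 0.15), MX1 (2.08 ± 0.12), IFIT1 (1.99 ± 0.11) and IFI44 (1.76 ± 0.17), all induced by type I interferon, rose most. Among antigen presentation genes, 11 of 16 measured members rose, 1 fell and 4 did not pass (13 and 1 adjusted over the list alone), and camera's adjusted p was 1.28e-08. The class I heavy chains HLA-B (1.53 ± 0.20) and HLA-F (1.37 ± 0.12) and the immunoproteasome subunits PSMB8 (1.21 ± 0.10) and PSMB10 (1.00 ± 0.12) were its largest changes. Among cholesterol biosynthesis genes, 12 of 18 measured members rose, 0 fell and 6 did not pass (16 and 0 adjusted over the list alone), and camera's adjusted p was 3.94e-11. Beside INSIG1, the enzymes MSMO1 (1.96 ± 0.12), HMGCS1 (1.50 ± 0.13) and LSS (1.27 ± 0.11) rose. Among genes of fatty acid synthesis and lipid droplets, 7 of 16 measured members rose, 2 fell and 7 did not pass (7 and 2 adjusted over the list alone), and camera's adjusted p was 0.0106, with an adjusted p of 0.159 with an estimated correlation. SCD and the acyl-CoA synthetase ACSL1 (1.62 ± 0.12) rose, as did the transcription factor SREBF1 (0.96 ± 0.18). Among NRF2 targets, 7 of 16 measured members rose, 1 fell and 8 did not pass (8 and 1 adjusted over the list alone), and camera's adjusted p was 0.000911. The reductase AKR1C2 rose most, followed by both subunits of the glutathione-synthesising ligase, GCLC (0.79 ± 0.11) and GCLM (0.71 ± 0.19).

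Among DNA replication genes, 9 of 23 measured members rose, 1 fell and 13 did not pass (11 and 2 adjusted over the list alone), and camera's adjusted p was 0.000128, with an adjusted p of 0.0729 with an estimated correlation; the members' mean of 0.29 turned to -0.02 with each array centred on its median. The replication helicase factors CDC45 (0.80 ± 0.12), MCM6 (0.78 ± 0.11) and MCM5 (0.78 ± 0.12) rose. Among lysosome and autophagy genes, 7 of 18 measured members rose, 1 fell and 10 did not pass (10 and 1 adjusted over the list alone), and camera's adjusted p was 0.000604, with an adjusted p of 0.0729 with an estimated correlation. The membrane protein LAMP2 (1.22 ± 0.11), the galactosidase GLA (1.05 ± 0.14) and the autophagy receptor SQSTM1 (0.97 ± 0.14) rose. Among heat shock genes, 6 of 13 measured members rose, 1 fell and 6 did not pass (6 and 1 adjusted over the list alone), and camera's adjusted p was 0.00565, with an adjusted p of 0.0641 with an estimated correlation; the members' mean of 0.32 turned to -0.02 with each array centred on its median. The chaperones HSPA1B (1.16 ± 0.12) and HSPA8 (0.95 ± 0.15) rose and the co-chaperone DNAJB1 fell (-1.11 ± 0.14). Among unfolded protein response genes, 5 of 15 measured members rose, 1 fell and 9 did not pass (5 and 1 adjusted over the list alone), and camera's adjusted p was 0.0183, with an adjusted p of 0.164 with an estimated correlation; the members' mean of 0.23 turned to -0.10 with each array centred on its median. The chaperone CALR (0.86 ± 0.13) rose most. Among genes of mitochondrial oxidative phosphorylation, 5 of 22 measured members rose, 0 fell and 17 did not pass (6 and 0 adjusted over the list alone), and camera's adjusted p was 0.0279, with an adjusted p of 0.0916 with an estimated correlation; the members' mean of 0.19 turned to -0.17 with each array centred on its median. ATP5MC1, a subunit of ATP synthase, rose by 0.88 ± 0.12.

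Among MAPK output and feedback genes, 1 of 19 measured members rose, 11 fell and 7 did not pass (1 and 12 adjusted over the list alone), and camera's adjusted p was 8.15e-07. The phosphatases DUSP5 (-1.99 ± 0.14) and DUSP6 (-1.29 ± 0.13), which act on ERK, fell, as did PHLDA1 (-2.24 ± 0.14) and the immediate early factor EGR1 (-1.14 ± 0.12). The member that rose was SPRY4, an inhibitor of receptor signalling (0.77 ± 0.13), for which none of the 3 other probes passed. Among genes of the amino acid response and serine synthesis, 0 of 24 measured members rose, 12 fell and 12 did not pass (1 and 14 adjusted over the list alone), and camera's adjusted p was 1.4e-07. The pseudokinase TRIB3 (-1.80 ± 0.17), the secreted STC2 (-1.17 ± 0.11) and the arginine carrier SLC7A1 (-1.14 ± 0.14) fell. Among TGF-beta targets, 0 of 13 measured members rose, 6 fell and 7 did not pass (0 and 6 adjusted over the list alone), and camera's adjusted p was 1.57e-05. PMEPA1 (-1.67 ± 0.12), a feedback inhibitor of this pathway, the matricellular protein CCN2 (-1.60 ± 0.12) and JUNB (-1.33 ± 0.12) fell. Among integrin and focal adhesion genes, 0 of 16 measured members rose, 8 fell and 8 did not pass (0 and 11 adjusted over the list alone), and camera's adjusted p was 2.73e-05. The subunits ITGB5 (-2.08 ± 0.12), ITGA2 (-1.18 ± 0.12) and ITGA3 (-0.83 ± 0.15) fell. Among cytosolic ribosomal proteins, 0 of 23 measured members rose, 5 fell and 18 did not pass (0 and 5 adjusted over the list alone), and camera's adjusted p was 0.0032. RPL13 (-0.73 ± 0.15) and RPL7 (-0.62 ± 0.19) fell most. At least 1 other probe did not pass for AKR1C2, HMGA1, HOPX, ITGA3, ITGB5, KIT, LAMP2, LSS, MSMO1, PSMB8, RPL13, SPRY4 and SREBF1. Another probe passed with a change over 1.5 times apart for ACSS2 (0.79), ATP5MC1 (0.37), ECM1 (0.62), HLA-F (0.89), INSIG1 (1.61), LAMP2 (0.61), PHLDA1 (-1.24), PMEPA1 (-0.64) and RNASE1 (1.55). The interferon, antigen presentation, cholesterol, NRF2, MAPK, ATF4, TGF-beta, integrin and ribosomal protein lists kept their call with an estimated correlation (9 of 15 lists), and the other 23 lists tested had camera adjusted p of 0.078 to 0.972. With array brightness in the fit 1142 genes passed, without GCLM, RPL7 and SREBF1. With each array centred on its median in place of quantile normalization, CDC45, MCM5, MCM6, GCLC, GCLM, SREBF1, HSPA8, CALR and ATP5MC1 did not pass, nor did the NRF2, heat shock, unfolded protein response and oxidative phosphorylation lists. Among genes above background on all 9 arrays the last 2 did not pass either, at unchanged means of 0.23 and 0.19, nor did oxidative phosphorylation with brightness in the fit (adjusted p = 0.0728) or with cyclic loess (0.057), or the unfolded protein response with external control probes as negative controls (0.0507).

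**Figure D2:**
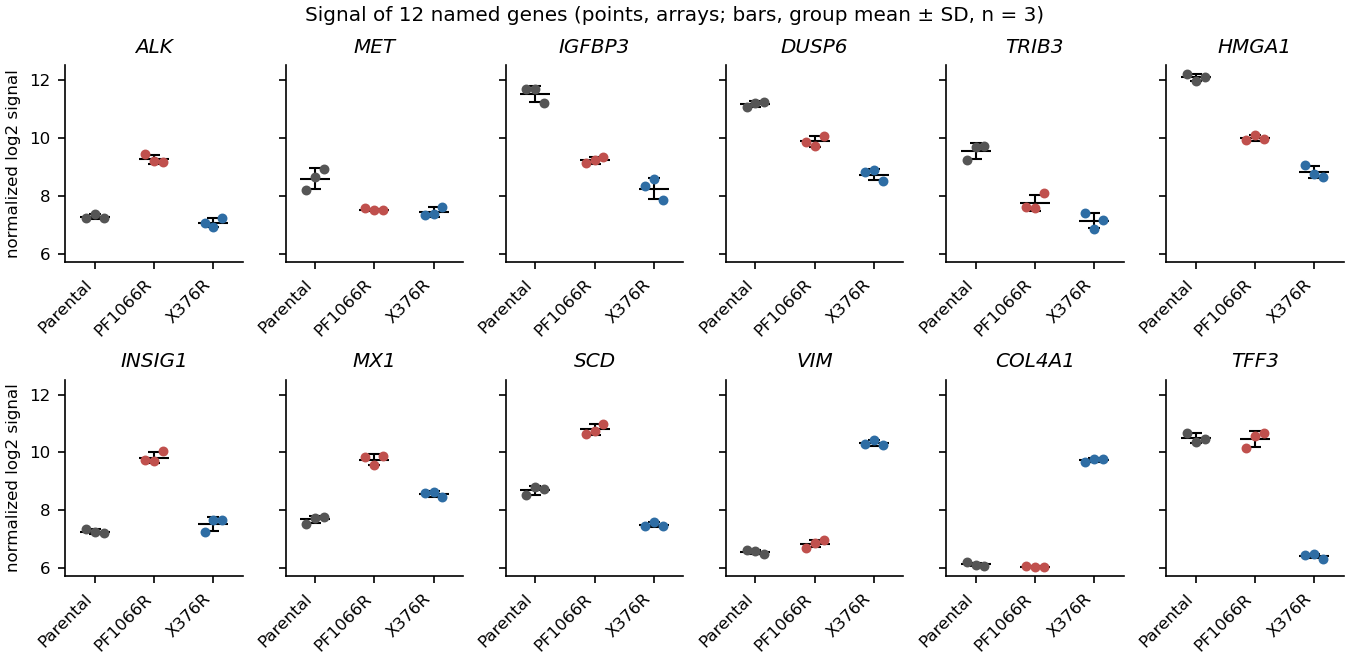
Normalized log2 signal of 12 genes on each array (points), with group mean and SD (bars), n = 3 arrays a line. The genes were picked from those of the naming rule after their values were seen, and ALK stands highest in PF1066R, VIM and COL4A1 in X376R.

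The second comparison asked the same of the line resistant to X-376. VIM, the intermediate filament of mesenchymal cells, was 13.6-fold higher in X376R (3.76 ± 0.11, adjusted p = 2.94e-13), and the collagen chains COL4A1 and COL5A1 were 12.2-fold and 10.1-fold higher. The trefoil peptide TFF3 was 17.0-fold lower (-4.09 ± 0.14). Targets of MAPK signalling and of ATF4 fell, and ALK gave -0.20 ± 0.12 (adjusted p = 0.251). In all, 3875 genes passed, 1926 higher and 1949 lower, and 536 of them differed by at least 2-fold (248 higher, 288 lower).

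COL4A1 rose by 3.61 ± 0.10 and COL5A1 by 3.34 ± 0.12; in Parental they lay above background on 2 and 1 of 3 arrays, so the size of their change is uncertain. Where a gene lay below background on every array of a line, its fold is a bound, taken from the bright line's mean against the higher of the background limit and the gene's own signal on each dim array, in log2 values. By that bound, CYP1A2, a monooxygenase of the same family as CYP1A1, was at least 11.3-fold higher (adjusted p = 4.8e-13) and the secreted lipocalin PAEP at least 10.5-fold (adjusted p = 1.12e-11). The protease inhibitor CST6 rose 8.33-fold (3.06 ± 0.14), ID3, an inhibitor of helix-loop-helix factors, 7.22-fold (2.85 ± 0.14), and the matricellular protein CCN1 6.69-fold (2.74 ± 0.12). The histone genes H2BC21 and H2BC5 rose 6.55-fold and 6.47-fold. H2AC18 and H2AC19 gave 3.59 ± 0.16 and 3.50 ± 0.16, but they are near-identical copies, so which of them each probe reads is uncertain. Among the decreases, the trefoil peptide TFF1 was at least 16.1-fold lower (adjusted p = 9.04e-14). BPIFA1, a secreted airway protein, fell 12.3-fold (-3.62 ± 0.16), the protease inhibitor SLPI 11.7-fold (-3.55 ± 0.14) and the NADPH oxidase subunit CYBA 11.4-fold (-3.52 ± 0.15). The alkaline phosphatase ALPL fell as well (-3.46 ± 0.13), the ERK phosphatase DUSP5 9.98-fold, the mucus protein FCGBP 9.87-fold and complement factor CFB 9.86-fold. IGFBP3 fell 9.72-fold (-3.28 ± 0.17), HMGA1 9.71-fold (-3.28 ± 0.12) and the tight junction protein CLDN10 9.36-fold (-3.23 ± 0.11).

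Among MAPK output and feedback genes, 0 of 19 measured members rose, 16 fell and 3 did not pass (1 and 16 adjusted over the list alone), and camera's adjusted p was 6.79e-10. DUSP5 (-3.32 ± 0.14), PHLDA1 (-3.07 ± 0.14), DUSP6 (-2.44 ± 0.13) and the transcription factor ETV5 (-1.25 ± 0.12) fell most. Among genes of the amino acid response and serine synthesis, 0 of 24 measured members rose, 14 fell and 10 did not pass (0 and 14 adjusted over the list alone), and camera's adjusted p was 2.51e-07. TRIB3 (-2.41 ± 0.17), the stress factor DDIT3 (-1.15 ± 0.16) and the asparagine synthetase ASNS (-1.15 ± 0.14) fell. Among NF-kappaB targets and inflammatory cytokines, 2 of 21 measured members rose, 10 fell and 9 did not pass (3 and 10 adjusted over the list alone), and camera's adjusted p was 0.00416, with an adjusted p of 0.0706 with an estimated correlation. The chemokine CCL20 (-1.97 ± 0.14), the prostaglandin synthase PTGS2 (-1.80 ± 0.14) and the chemokine CXCL8 (-1.55 ± 0.15) fell. Among cytosolic ribosomal proteins, 0 of 23 measured members rose, 10 fell and 13 did not pass (0 and 11 adjusted over the list alone), and camera's adjusted p was 0.00755, with an adjusted p of 0.074 with an estimated correlation. RPL13 (-0.97 ± 0.15) and RPL7 (-0.85 ± 0.19) fell most. Among cholesterol biosynthesis genes, 7 of 18 measured members rose, 1 fell and 10 did not pass (8 and 1 adjusted over the list alone), and camera's adjusted p was 0.00416, with an adjusted p of 0.0706 with an estimated correlation; the members' mean of 0.36 turned to -0.02 with each array centred on its median. LSS (1.30 ± 0.11) and MSMO1 (0.99 ± 0.12) rose. Among DNA replication genes, 17 of 23 measured members rose, 0 fell and 6 did not pass (18 and 1 adjusted over the list alone), and camera's adjusted p was 1.21e-07, with an adjusted p of 0.07 with an estimated correlation. The thymidylate synthase TYMS (1.40 ± 0.12), MCM2 (1.28 ± 0.14) and MCM5 (1.26 ± 0.12) rose most. Among lysosome and autophagy genes, 12 of 18 measured members rose, 1 fell and 5 did not pass (12 and 1 adjusted over the list alone), and camera's adjusted p was 3.79e-05, with an adjusted p of 0.0706 with an estimated correlation. LAMP2 (1.54 ± 0.11) and the proteases CTSA (1.28 ± 0.11) and CTSL (1.26 ± 0.14) rose most.

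Among TGF-beta targets, 9 of 13 measured members rose, 2 fell and 2 did not pass (9 and 2 adjusted over the list alone), and camera's adjusted p was 0.00131, with an adjusted p of 0.089 with an estimated correlation. ID3 (2.85 ± 0.14) and the matrix protein TGFBI (2.22 ± 0.14) rose, and the transcription factor BHLHE40 fell (-1.20 ± 0.12). Among YAP and TEAD targets, 8 of 14 measured members rose, 1 fell and 5 did not pass (9 and 1 adjusted over the list alone), and camera's adjusted p was 0.00131, with an adjusted p of 0.216 with an estimated correlation. CCN1 rose by 2.74 ± 0.12 and the receptor AXL by 1.12 ± 0.12, while the ectonucleotidase NT5E fell (-1.62 ± 0.11). Among mesenchymal markers, 6 of 15 measured members rose, 1 fell and 8 did not pass (6 and 1 adjusted over the list alone), and camera's adjusted p was 0.00816, with an adjusted p of 0.104 with an estimated correlation. Beside VIM and TGFBI, the actin-binding TAGLN was at least 3.94-fold higher (adjusted p = 4.29e-09), and S100A4 fell (-1.86 ± 0.13). Among fibroblast and stromal markers, 4 of 9 measured members rose, 0 fell and 5 did not pass (4 and 0 adjusted over the list alone), and camera's adjusted p was 0.0112, with an adjusted p of 0.089 with an estimated correlation. COL5A1 rose by 3.34 ± 0.12, COL1A1 by 0.83 ± 0.12, and the matrix protein FBLN1 by 0.54 ± 0.13, and the proteoglycan LUM was at least 1.39-fold higher (adjusted p = 0.0217). Among receptor tyrosine kinase ligands, 6 of 22 measured members rose, 2 fell and 14 did not pass (6 and 2 adjusted over the list alone), and camera's adjusted p was 0.0192, with an adjusted p of 0.089 with an estimated correlation. GAS6, the ligand of AXL (1.89 ± 0.11), EFNA1 (1.74 ± 0.13) and VEGFC (1.61 ± 0.10) rose. Among genes of cytochrome P450, UGT and glutathione enzymes, 7 of 15 measured members rose, 1 fell and 7 did not pass (7 and 2 adjusted over the list alone), and camera's adjusted p was 0.0285, with an adjusted p of 0.104 with an estimated correlation. CYP1A1 (2.48 ± 0.15) and CYP1B1 (1.48 ± 0.12) rose. Extracellular matrix and protease genes had 7 members that rose and 5 that fell of 21, among them the matrix protein THBS1 at 2.27 ± 0.13, and camera's adjusted p was 0.147. Among interferon response genes 8 rose, 7 fell and 12 did not pass of 27, and camera's adjusted p was 0.806; IFITM2 fell most (-2.01 ± 0.13) and IFI6 rose (1.23 ± 0.15). Among the p53 targets 9 rose, 2 fell and 5 did not pass of 16, and camera's adjusted p was 0.185; GDF15 fell most (-3.18 ± 0.12) and TP53I3 rose (2.25 ± 0.16). The epithelial cadherin CDH1, outside the naming rule and chosen after its values were seen, fell (-0.88 ± 0.12). AXL, GAS6, THBS1 and VEGFC lay above background on 1 of 3 Parental arrays, so the size of their change is uncertain. In X376R, at least 1 other probe did not pass for ACSS2, CTSL, FBLN1, HOPX, LAMP2, LSS, MSMO1 and RPL13. Another probe passed there with a change over 1.5 times apart for ASNS (-0.76), ECM1 (1.38), ETV5 (-0.38), FBLN1 (0.35), HMGA1 (-0.52), LAMP2 (0.66 and 0.82), PHLDA1 (-1.66), PTGS2 (-1.19) and TAGLN (0.88). The MAPK and ATF4 lists kept their call with an estimated correlation (2 of 13 lists), and the other 25 lists tested had camera adjusted p of 0.0582 to 0.89. With array brightness in the fit 1149 genes passed, without CDH1, COL1A1, DDIT3, FBLN1, KRT7, LUM and RPL7. With each array centred on its median FBLN1, IFI6, LUM and MSMO1 did not pass, nor did the cholesterol and cytochrome lists. With brightness in the fit the cytochrome list did not pass either (adjusted p = 0.177), nor with no filter (0.122) or the 95th percentile as background limit (0.0679). Among genes above background on all 9 arrays the mesenchymal, fibroblast, kinase ligand and YAP lists did not pass, with means of 1.05, 0.68, 0.41 and 0.44 there against 0.63, 0.61, 0.34 and 0.49.

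The third comparison set X376R directly against PF1066R, which is also the test of whether the lines' changes from Parental differ. ALK was 4.55-fold lower in X376R (-2.19 ± 0.12, adjusted p = 6.74e-10) and EML4 1.40-fold (-0.49 ± 0.13, adjusted p = 0.0152). COL4A1 was 12.9-fold higher in X376R (3.69 ± 0.10), VIM 11.2-fold (3.48 ± 0.11) and COL5A1 9.87-fold (3.30 ± 0.12); COL4A1 and COL5A1 lay above background on 1 of 3 PF1066R arrays, so the size of their change is uncertain. Interferon-stimulated and lipid synthesis genes were lower in X376R, and targets of TGF-beta higher. In all, 2213 genes passed, 1098 higher and 1115 lower in X376R, 274 of them by at least 2-fold (134 higher, 140 lower). CST6 was 12.4-fold higher (3.64 ± 0.14), TGFBI 10.1-fold (3.34 ± 0.14), the galectin LGALS1 10.1-fold (3.33 ± 0.18) and CCN1 8.64-fold (3.11 ± 0.12), while H2AC19 gave 2.99 ± 0.16, uncertain as above. TFF3 was 16.7-fold lower (-4.06 ± 0.14), ALDH3A1 12.7-fold (-3.67 ± 0.12), SCD 9.80-fold (-3.29 ± 0.12) and the airway secretory protein BPIFB1 9.61-fold (-3.26 ± 0.13). The interferon-induced IFI27 was 9.37-fold lower (-3.23 ± 0.12), TFF1 at least 7.63-fold (adjusted p = 2.15e-12), the mucin-folding disulfide isomerase AGR2 7.67-fold (-2.94 ± 0.15) and the stress cytokine GDF15 6.37-fold (-2.67 ± 0.12). ALDH3A1 and IFI27 lay above background on 2 of 3 X376R arrays.

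Among TGF-beta targets, 11 of 13 measured members were higher, 0 lower and 2 did not pass (11 and 0 adjusted over the list alone), and camera's adjusted p was 1.22e-13. PMEPA1 (2.77 ± 0.12) and CCN2 (2.70 ± 0.12) were higher with TGFBI. Among mesenchymal markers, 6 of 15 measured members were higher, 1 lower and 8 did not pass (6 and 1 adjusted over the list alone), and camera's adjusted p was 3.97e-05. The cadherin CDH2 was higher by 2.36 ± 0.11. Among extracellular matrix and protease genes, 10 of 21 measured members were higher, 2 lower and 9 did not pass (11 and 3 adjusted over the list alone), and camera's adjusted p was 3.97e-05. THBS1 (2.27 ± 0.13) and TIMP2 (2.23 ± 0.21) were higher in X376R. Among receptor tyrosine kinase ligands, 8 of 22 measured members were higher, 2 lower and 12 did not pass (8 and 2 adjusted over the list alone), and camera's adjusted p was 0.00377. GAS6 was at least 3.60-fold higher (adjusted p = 5.07e-10) and HBEGF at least 2.41-fold (adjusted p = 4.42e-08). Among fibroblast and stromal markers, 3 of 9 measured members were higher, 0 lower and 6 did not pass (4 and 0 adjusted over the list alone), and camera's adjusted p was 0.00545, with an adjusted p of 0.0579 with an estimated correlation. COL1A1 was higher by 0.85 ± 0.12. Among YAP and TEAD targets, 6 of 14 measured members were higher, 1 lower and 7 did not pass (6 and 1 adjusted over the list alone), and camera's adjusted p was 0.000135, with an adjusted p of 0.109 with an estimated correlation. AXL was higher by 1.06 ± 0.12. Among integrin and focal adhesion genes, 7 of 16 measured members were higher, 1 lower and 8 did not pass (9 and 1 adjusted over the list alone), and camera's adjusted p was 0.000639, with an adjusted p of 0.0546 with an estimated correlation. The caveolae protein CAV1 was 4.45-fold higher and ITGA3 3.05-fold. Among DNA replication genes, 9 of 23 measured members were higher, 0 lower and 14 did not pass (10 and 0 adjusted over the list alone), and camera's adjusted p was 0.000317, with an adjusted p of 0.0797 with an estimated correlation. TYMS was higher by 1.04 ± 0.12. Among p53 targets, 7 of 16 measured members were higher, 2 lower and 7 did not pass (8 and 2 adjusted over the list alone), and camera's adjusted p was 0.0198, with an adjusted p of 0.0805 with an estimated correlation. TP53I3 was higher (1.99 ± 0.16), and GDF15 (-2.67 ± 0.12) and the death receptor TNFRSF10B (-1.14 ± 0.14) were lower. CDH2, THBS1, AXL and CAV1 lay above background on 1 of 3 PF1066R arrays, so the size of their difference is uncertain. Among genes above background on all 9 arrays the matrix, kinase ligand and p53 lists did not pass, with means of 0.23, 0.20 and 0.16 there against 0.64, 0.31 and 0.16.

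Among interferon response genes, 0 of 27 measured members were higher, 17 lower and 10 did not pass (0 and 19 adjusted over the list alone), and camera's adjusted p was 9.89e-17. IFI27 (-3.23 ± 0.12), IFI44 (-1.88 ± 0.17), IFITM1 (-1.83 ± 0.15) and OAS1 (-1.64 ± 0.12) were the lowest in X376R, where IFITM1 lay above background on 1 of 3 arrays. Among antigen presentation genes, 0 of 16 measured members were higher, 8 lower and 8 did not pass (0 and 9 adjusted over the list alone), and camera's adjusted p was 2.43e-05. HLA-B (-1.01 ± 0.20) and the peptide transporter TAP1 (-0.83 ± 0.10) were lower. Among genes of fatty acid synthesis and lipid droplets, 0 of 16 measured members were higher, 6 lower and 10 did not pass (0 and 8 adjusted over the list alone), and camera's adjusted p was 5.28e-05. LPIN1 (-1.87 ± 0.12) and SREBF1 (-1.86 ± 0.18) were lower with SCD. Among cholesterol biosynthesis genes, 0 of 18 measured members were higher, 6 lower and 12 did not pass (0 and 8 adjusted over the list alone), and camera's adjusted p was 8.42e-05. INSIG1 was lower (-2.30 ± 0.13). Among MAPK output and feedback genes, 2 of 19 measured members were higher, 9 lower and 8 did not pass (2 and 10 adjusted over the list alone), and camera's adjusted p was 0.000285. SPRY4 (-1.78 ± 0.13), DUSP5 (-1.33 ± 0.14) and DUSP6 (-1.15 ± 0.13) were lower. Among NRF2 targets, 1 of 16 measured members were higher, 8 lower and 7 did not pass (1 and 8 adjusted over the list alone), and camera's adjusted p was 0.000393. AKR1C2 (-2.32 ± 0.12) and the thioredoxin reductase TXNRD1 (-0.95 ± 0.14) were lower. Among NF-kappaB targets and inflammatory cytokines, 2 of 21 measured members were higher, 8 lower and 11 did not pass (2 and 9 adjusted over the list alone), and camera's adjusted p was 0.00377. CCL20 (-2.42 ± 0.14) and PTGS2 (-1.64 ± 0.14) were lower. Among genes of the hypoxia response and glycolysis, 2 of 25 measured members were higher, 11 lower and 12 did not pass (2 and 12 adjusted over the list alone), and camera's adjusted p was 5.14e-05, with an adjusted p of 0.0892 with an estimated correlation. NDRG1 (-2.23 ± 0.19), induced by hypoxia, and the hexokinase HK2 (-1.62 ± 0.13) were lower. Among unfolded protein response genes, 0 of 15 measured members were higher, 6 lower and 9 did not pass (0 and 6 adjusted over the list alone), and camera's adjusted p was 0.0037, with an adjusted p of 0.0892 with an estimated correlation. The transcription factor XBP1 was lower (-0.83 ± 0.13). Between the lines, at least 1 other probe did not pass for AKR1C2, EGFR, ERBB3, HMGA1, IGFBP3, ITGA3, SPRY4 and TNFRSF10B. Another probe passed with a difference over 1.5 times apart for CAV1 (0.42), ERBB3 (-0.67), HK2 (-0.90), INSIG1 (-1.43), OAS1 (-0.90), PHLDA1 (-0.42), PMEPA1 (1.15), SPRY4 (-0.44), SREBF1 (-0.71) and TIMP2 (0.59). With an estimated correlation 11 of the 18 lists kept their call: TGF-beta, mesenchymal, matrix and kinase ligand lists higher, and interferon, antigen presentation, fatty acid, cholesterol, MAPK, NRF2 and NF-kappaB lists lower. The other 20 lists tested had camera adjusted p of 0.103 to 0.951. With each array centred on its median in place of quantile normalization 978 genes passed. On arrays of matched brightness, PF1066R replicates 2 and 3 with all X376R arrays, 1427 passed in a fit on fewer arrays.

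**Figure D3:**
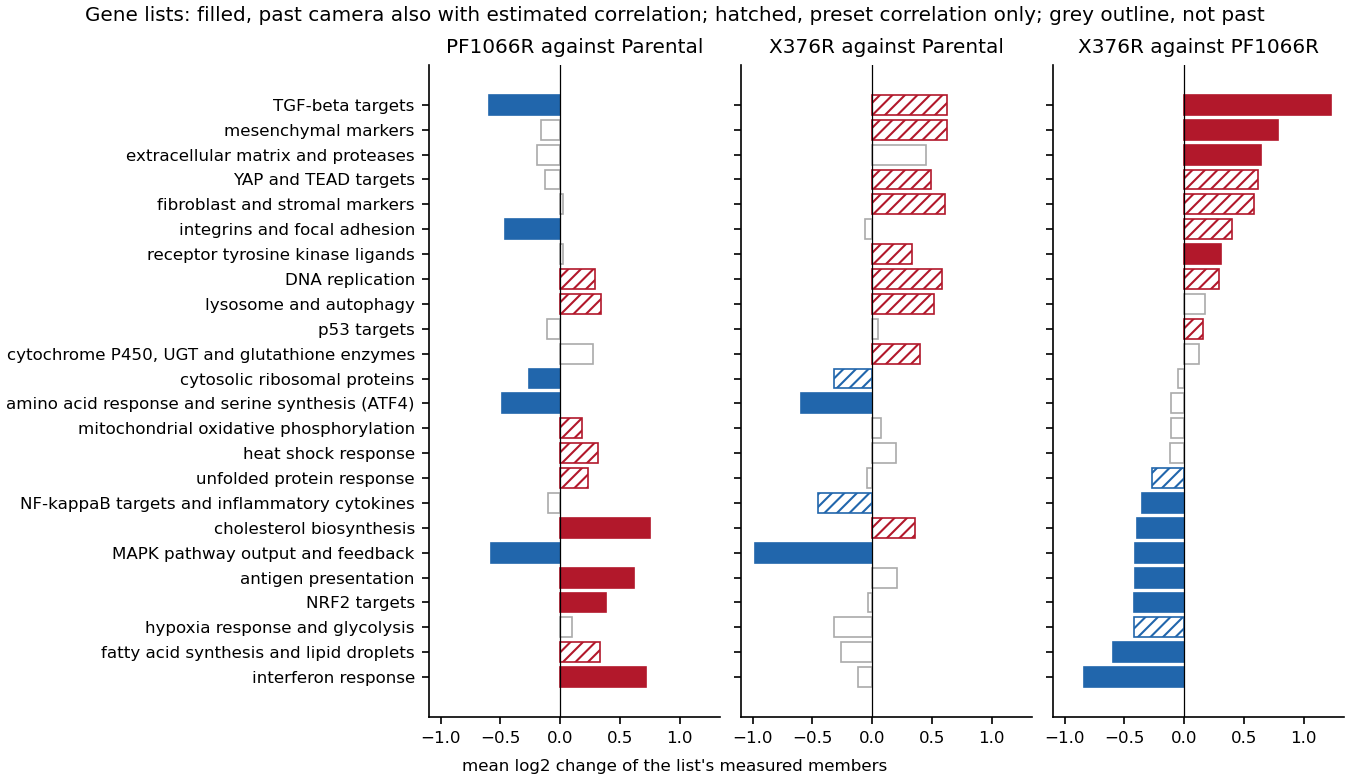
Mean log2 change of the measured members of the 24 lists that passed camera in at least 1 comparison, with a panel for each comparison. Filled bars passed also with an estimated correlation, hatched bars with the preset correlation alone, and grey outlines did not pass; red is higher and blue lower in the line named first.

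A set of 1645 genes passed in both resistant lines in the same direction, 758 higher and 887 lower than in Parental, and 85 passed in opposite directions. Lists of these sizes drawn independently would share 175 higher and 182 lower genes, and unchanged groups simulated against the same Parental arrays shared 0.01 genes on average. Across genes, which are not independent replicates, the lines' log2 changes correlated with r = 0.616 and had a covariance of 0.0940. Simulated unchanged groups gave r of 0.501 and a covariance of 0.00795, both from the shared Parental arrays alone. That r holds for noise and is no share of 0.616, whereas 0.0860 of the covariance lay beyond the simulated part. Part of the excess over independent lists may come from the shared controls, since 3 Parental arrays are too few to split into groups of 2. Of the 1645 genes, 368 also differed between the lines, with 290 changed further in X376R and 78 in PF1066R. ACSS2 rose by 2.39 ± 0.15 in PF1066R and 2.05 ± 0.15 in X376R, and CYP1A1 by 2.01 ± 0.15 and 2.48 ± 0.15. The secreted matrix protein ECM1 (1.80 ± 0.13 and 2.07 ± 0.13), the channel subunit LRRC26 (1.80 ± 0.15 and 1.55 ± 0.15) and the transcription factor SOX2 (1.63 ± 0.13 and 1.48 ± 0.13) rose in both, as did NDRG2 (1.48 ± 0.16 and 2.32 ± 0.16) and the endothelial cadherin CDH5 (1.41 ± 0.13 and 2.26 ± 0.13, above background on 1 of 3 Parental arrays). HOPX, a homeodomain protein of the lung epithelium, was at least 2.32-fold higher in PF1066R (adjusted p = 1.51e-07) and at least 4.20-fold in X376R (adjusted p = 1.69e-10), and its other probe passed in neither. SERPINA3 fell (-2.83 ± 0.16 in PF1066R and -2.87 ± 0.16 in X376R), as did MAT2A (-2.32 ± 0.14 and -2.67 ± 0.14), STMN3 (-2.31 ± 0.15 and -2.33 ± 0.15) and ODC1 (-2.21 ± 0.11 and -2.10 ± 0.11). IGFBP3, PHLDA1 and HMGA1 fell in both and further in X376R (-0.98 ± 0.17, -0.83 ± 0.14 and -1.18 ± 0.12 against PF1066R). MUC2 fell in PF1066R (-1.99 ± 0.13) and was at least 4.98-fold lower in X376R (adjusted p = 4.13e-10). With array brightness in the fit 531 genes passed in both in the same direction.

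**Figure D4:**
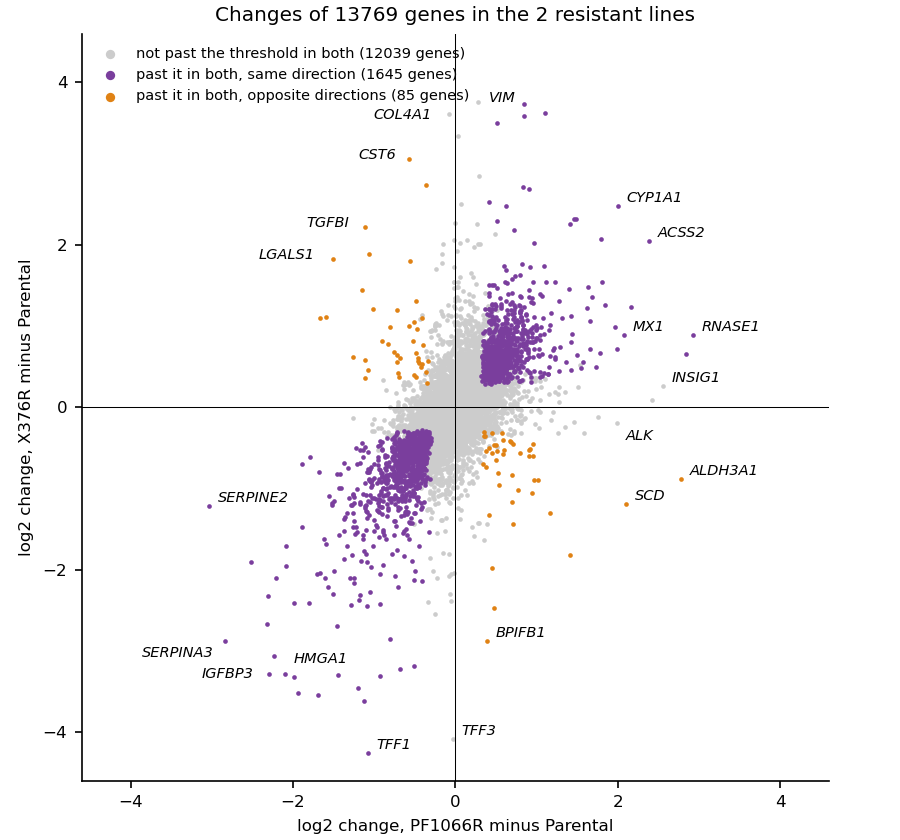
Log2 change from Parental of 13769 genes in PF1066R (horizontal) and X376R (vertical), each point a gene, fitted on 3 arrays a line. Purple points (1645) passed in both in the same direction and orange points (85) in opposite directions; genes below background, such as TFF1 in X376R, are drawn at their fitted value.

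Receptors of the insulin and growth factor families were named for every comparison. MET, the hepatocyte growth factor receptor, fell in PF1066R (-1.08 ± 0.15, adjusted p = 7.93e-05) and in X376R (-1.15 ± 0.15, adjusted p = 1.86e-05), and gave -0.07 ± 0.15 between the lines (adjusted p = 0.819). KIT rose by 0.46 ± 0.12 in PF1066R (adjusted p = 0.0099) and 0.49 ± 0.12 in X376R (adjusted p = 0.00393), and gave 0.03 ± 0.12 between them (adjusted p = 0.914). EGFR gave 0.22 ± 0.11 (adjusted p = 0.226) and -0.20 ± 0.11 (adjusted p = 0.223) against Parental and was lower in X376R than in PF1066R (-0.42 ± 0.11, adjusted p = 0.0179). ERBB3 gave 0.25 ± 0.12 (adjusted p = 0.173) and -0.16 ± 0.12 (adjusted p = 0.385), and was lower in X376R than in PF1066R (-0.41 ± 0.12, adjusted p = 0.0261). The receptor IGF1R gave -0.12 ± 0.10 in PF1066R (adjusted p = 0.492), above background there on 1 of 3 arrays. In X376R, IGF1R lay above background on 0 of 3 arrays and gave -0.15 (adjusted p = 0.312). Its adaptor IRS1 gave 0.25 ± 0.12 in PF1066R (adjusted p = 0.187) and rose by 0.39 ± 0.12 in X376R (adjusted p = 0.0224). IRS2 gave -0.05 ± 0.13 (adjusted p = 0.884) and 0.06 ± 0.13 (adjusted p = 0.798). Between the resistant lines IGF1R gave -0.03 (adjusted p = 0.901), IRS1 0.14 ± 0.12 (adjusted p = 0.51) and IRS2 0.11 ± 0.13 (adjusted p = 0.68). EML4 fell in X376R against Parental (-0.48 ± 0.13, adjusted p = 0.0102). With array brightness in the fit, MET (-0.83), KIT (0.65) and EML4 (-0.62) in X376R and EGFR (-0.42) and ERBB3 (-0.42) between the lines did not pass, and only MET's change was smaller there. With each array centred on its median, KIT did not pass in either line, IRS1 did not in X376R, nor EGFR and ERBB3 between the lines, while ALK, EGFR and ERBB3 passed as lower in X376R than in Parental. No probe of the insulin receptor gene INSR passed the filter.

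The remaining 14 lists tested passed in no comparison; the numbers below are in the order PF1066R against Parental, X376R against Parental and X376R against PF1066R. For the IGF1R and insulin receptor pathway, 1, 3 and 4 rose and 5, 4 and 3 fell of 17 measured. IGFBP3 fell in both lines, and IGFBP7 rose in X376R (1.92 ± 0.11). For other receptor tyrosine kinases, 3, 5 and 2 rose and 2, 3 and 4 fell of 17 measured. Beside MET, EPHA2 fell in PF1066R (-1.07 ± 0.12), and AXL rose in X376R (1.12 ± 0.12). For the PI3K, AKT and mTOR pathway, 0, 4 and 4 rose and 1, 4 and 1 fell of 18 measured. DDIT4, an inhibitor of mTOR, fell in PF1066R (-1.09 ± 0.20) and in X376R (-2.44 ± 0.20). For epithelial markers, 3, 4 and 4 rose and 2, 5 and 7 fell of 20 measured. The mucin MUC1 rose in PF1066R (1.78 ± 0.14), and the keratin KRT7 in X376R (1.09 ± 0.15). For lung lineage markers, 3, 2 and 3 rose and 0, 0 and 1 fell of 16 measured. The lineage factor NKX2-1 rose in PF1066R (0.72 ± 0.12) and in X376R (1.20 ± 0.12). For aldehyde dehydrogenases and stem cell markers, 4, 4 and 4 rose and 5, 7 and 3 fell of 15 measured. ALDH2 fell in X376R (-2.42 ± 0.11). For proliferation and mitosis genes, 1, 4 and 1 rose and 2, 1 and 1 fell of 24 measured. For BCL2 family and apoptosis genes, 1, 3 and 5 rose and 6, 1 and 2 fell of 18 measured. The regulator CFLAR rose in PF1066R (0.99 ± 0.13), and the pro-apoptotic BIK fell in X376R (-1.40 ± 0.11). For Wnt targets and regulators, 1, 3 and 2 rose and 3, 4 and 1 fell of 15 measured. For drug efflux transporters, 2, 2 and 2 rose and 1, 2 and 2 fell of 9 measured. The transporter ABCC3 fell in PF1066R (-0.90 ± 0.14) and in X376R (-1.09 ± 0.14). For squamous markers, 1, 2 and 1 rose and 0, 1 and 1 fell of 6 measured. For neuroendocrine markers, 0, 1 and 0 rose and 1, 1 and 0 fell of 5 measured. For leukocyte markers, 1, 1 and 0 rose and 0, 0 and 1 fell of 11 measured. Of 13 cancer testis genes measured, 0 passed in any comparison. With each array centred on its median, NKX2-1 in PF1066R and KRT7 in X376R did not pass. The ALK fusion list has 2 members and was not tested as a list. Median, mean and camera direction differed in sign for 4, 8 and 5 lists, none of them past the threshold.

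Counts of genes whose 3 arrays in one line all lay above the 3 of the other were 4643 (33.7%) for PF1066R against Parental, 5338 (38.8%) for X376R against Parental and 4011 (29.1%) for X376R against PF1066R, where chance gives 10%. At an unadjusted p under 0.05, 4014, 5095 and 3754 genes passed. The split into higher and lower depends on the scaling. With each array centred on its median, the median of all tested genes moved by -0.12, -0.19 and -0.06 on the log2 scale, and 215 of 2439 genes were higher in PF1066R than in Parental, 388 of 4587 in X376R than in Parental and 275 of 978 in X376R than in PF1066R. Quantile normalization gives all arrays the same signal distribution, and the directions given here are relative to it.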

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

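The tests of array brightness and of fibroblast transcripts were chosen after the results they bear on were seen. The resistant lines differed in direction for 85 genes that passed against Parental in both, as 43 were higher in PF1066R and lower in X376R and 42 the reverse. Among these 85 genes, the largest differences for the genes named were ALDH3A1 at -3.67, CST6 at 3.64, TGFBI at 3.34, LGALS1 at 3.33, SCD at -3.29 and BPIFB1 at -3.26, X376R minus PF1066R. The mean of the TGF-beta targets differed by 1.23, being lower than Parental in PF1066R and higher in X376R. The list's rise in X376R did not pass camera with an estimated correlation (adjusted p = 0.089). For BPIFB1 the rise in PF1066R was small (0.39) and did not pass with array brightness in the fit (adjusted p = 0.508, with 0.0098 to 0.993 over 24 alternatives).

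Probes with no gene name stood outside the gene counts, and of 8239 such probes 440 changed in PF1066R and 757 in X376R against Parental. What these probes read is not given in the sources used here.

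The resistant lines' arrays were dimmer, which could add to the calls against Parental. With log2 mean signal in the fit, the called genes kept a median ratio of 0.991 ± 0.00539 of their change in X376R, 99.4% of them with the same sign, and 0.993 ± 0.00395 in PF1066R, 100% with the same sign. These errors come from resampling the called genes, which share the same arrays, so they leave out the uncertainty between arrays. Among the 2752 and 1443 calls that ended, standard errors grew 1.89 times and 1.42 times, since brightness and line overlap, and the change kept a median ratio of 0.909 and 0.918, with 31.2% and 23.4% of them under 0.75. Where arrays were centred on their median over all probes, the array medians of the tested genes shifted by -0.289 on average from Parental to X376R. The slope on brightness within lines predicts -0.320 ± 0.0271. Brightness is the mean of the same signals, so shift and brightness are tied by construction. The prediction therefore cannot tell an array effect from a difference between the lines. A difference in total RNA per cell was not measured and stays open, as does a biological difference between the lines.

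VIM, COL4A1 and COL5A1 rose in X376R, and fibroblasts among the cells are a candidate source. Across 13 fibroblast transcripts, all 9 measured members of the fibroblast list with SPARC, FN1, POSTN and TAGLN, the median log2 change was 0.170 ± 0.184, which does not decide. That error is from resampling these transcripts. By fitted value, COL5A1 (3.34), TAGLN (2.06), COL1A1 (0.83), FBLN1 (0.54) and LUM (0.52) passed, while COL1A2 (-0.11), COL3A1 (0.21), COL6A3 (-0.01), DCN (0.17), FAP (0.01), FN1 (0.12), POSTN (-0.19) and SPARC (0.01) did not. SPARC and POSTN lay above background on 0 of 3 X376R arrays, and COL1A2, COL3A1, COL6A3, DCN and FN1 on 1. Fibroblasts and a change of state in the resistant cells both stay open.

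ALK was higher in PF1066R by 1.99, and a gain of the region around it is a candidate cause. The 10 tested genes on each side of ALK had a median change of 0.00531 ± 0.0423, an error from resampling these genes. RBKS (0.37), BABAM2 (0.42) and LBH (0.51) rose past the threshold and none fell past it. In X376R, where ALK did not rise, these genes gave 0.62, 0.43 and 1.47. The median argues against a large gain that spans all the tested neighbours in their reference order. These cells carry an EML4-ALK fusion, so on the fusion copy the genes beside ALK may be others, and a gain there stays open. Changes of dim genes are shrunk, so a small gain is not ruled out. A gain that is narrower than the distance to the tested neighbours, or a change in transcription, stays open, since DNA was not measured.

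Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. The real split alone, 1 of 10, gave as many genes: 2539 in PF1066R against Parental, 3875 in X376R against Parental and 2213 in X376R against PF1066R, with 0 as the highest of the other splits each time. For lists, too, only the real split, 1 of 10, gave as many, with 15, 13 and 18 against a highest other of 10, 4 and 7. For genes changed in both resistant lines, 1 of 100 assignments of the 9 arrays to 3 groups, the real one, gave as many genes (1645, highest other 955). Most other assignments mix arrays of different lines, which any difference between the lines' arrays would turn into spread. The count therefore shows that the lines' arrays differ, and cannot tell whether the resistant lines share changes.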

How the results depend on the processing

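The brightness settings, the smaller offset and the external control probes as negative controls were chosen after the data were seen. The number of genes changed moved by more than 1.5 times in few settings. With an adjusted p under 0.01 there were 1487 genes in PF1066R against Parental, 1259 between the resistant lines and 933 in both lines. With an absolute log2 change of at least 1 there were 235 in PF1066R, 536 in X376R, 274 between the lines and 115 in both, and these smaller numbers follow from the stricter thresholds. With brightness as a covariate there were 1142 in PF1066R, 1149 in X376R and 531 in both, with r of 0.657, and on arrays of matched brightness 1162 in PF1066R against Parental and 1427 between the lines. Median centring gave 978 genes between the lines and r of 0.718, and cyclic loess r of 0.664. The causes of these last differences and of the one with matched arrays were not tested.

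An estimated correlation left 9 lists in PF1066R, 2 in X376R and 11 between the lines of 15, 13 and 18, and fry gave 29 in PF1066R and 23 in X376R. Extracellular matrix genes in X376R turned from a higher to a lower mean of -0.49 among genes above background on all 9 arrays (adjusted p = 0.0474, at most 0.354 over 25 alternatives), a filter that drops genes such as COL5A1, above background on 1 of 3 Parental arrays. The list passed as higher in X376R with median centring (mean 0.18, adjusted p = 0.00131), external control probes as negative controls (0.70, 0.049) and fry (0.45, 4.12e-05). That filter also ended 9 calls for lists: matrix (adjusted p = 0.247), kinase ligands (0.209) and p53 targets (0.128) between the lines, mesenchymal (0.178), fibroblast (0.123), kinase ligand (0.123) and YAP (0.152) lists in X376R, and oxidative phosphorylation (0.0802) and the unfolded protein response (0.0589) in PF1066R. In PF1066R it added the cytochrome (0.00474), matrix (0.000847) and squamous (0.0387) lists.

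Other probes of a gene gave the opposite sign or 0 for RPL13 (0.11), LAMP2 (-0.12) and MSMO1 (-0.067) in PF1066R, for FBLN1 (0), RPL13 (0.22), ITGB5 (0.088) and MSMO1 (-0.13) in X376R and for FBLN1 (-0.29) between the lines. The cause was not tested. Of 287 calls for genes named in the text, 205 passed under every alternative run for them, 79 did not under at least 1, and 8, some of them among the 79, changed sign by another probe. Of 46 calls for lists, 19 passed under every alternative and 27 did not under at least 1. Median centring ended 39 calls of named genes and brightness as a covariate 28.

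Without 1 array at a time, genes changed ranged from 1871 to 2796 in PF1066R, 3112 to 3841 in X376R, 1618 to 2203 between the lines and 1187 to 1678 in both. Lists ranged from 15 to 16, 13 to 14 and 18 to 19, and r from 0.595 to 0.639. Of the calls for named genes, 16 ended without at least 1 array, and 2 appeared. In PF1066R, GCLM did not pass without PF1066R replicate 1 (adjusted p = 0.0779) or 2 (0.0671), and RPL7 without PF1066R replicate 2 (0.151) or 3 (0.0681) or Parental replicate 1 (0.0592) or 3 (0.152). BPIFB1 did not pass there without PF1066R replicate 1 (0.115), 2 (0.0578) or 3 (0.106) or Parental replicate 3 (0.247). In X376R, EML4 did not pass without Parental replicate 1 (0.062) or X376R replicate 1 (0.0601), LUM without Parental replicate 3 (0.0848) or X376R replicate 3 (0.113), and IRS1 without Parental replicate 1 (0.0951) or 2 (0.059) or X376R replicate 1 (0.11). Between the lines, EML4 did not pass without PF1066R replicate 3 (0.0828) or X376R replicate 1 (0.0808), EGFR without PF1066R replicate 3 (0.094) or X376R replicate 2 (0.077), and ERBB3 without PF1066R replicate 1 (0.0902) or 3 (0.0936) or X376R replicate 1 (0.0532) or 2 (0.111). The hypoxia list passed in X376R without Parental replicate 2 (0.0333) or 3 (0.0487), PF1066R replicate 1 (0.0376) or X376R replicate 1 (0.0465), and in PF1066R without PF1066R replicate 1 (0.022). In X376R it passed under 11 of 25 alternatives in all, among them median centring (0.00239), brightness as a covariate (0.0151), no filter (0.0306), the offset of 16 (0.0386), external controls (0.0407), the deposited values (0.0499) and fry (0.00821). Lysosome genes passed between the lines without PF1066R replicate 3 (0.0227) or X376R replicate 3 (0.0396), and cytochrome enzymes in PF1066R without X376R replicate 3 (0.0478).

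With the replicate number as a block, 2886, 4167 and 2477 genes changed, 1894 in both, and r was 0.616. Lists past the threshold numbered 16, 13 and 18, the added one being cytochrome P450, UGT and glutathione enzymes in PF1066R (adjusted p = 0.0403). Deviations of arrays with the same number correlated at r of -0.0481 to 0.221, over 0.1 in 5 of 9 pairs, and 5 of 9 arrays correlated best with their own number, so by the rule used, every pair over 0.1, the arrays were not treated as paired. All 3 pairs of replicate 2 (0.144 to 0.221) and 2 of 3 pairs of replicate 3 (0.110 and 0.146) lay over 0.1, and replicate 2 of one line with replicate 3 of another gave -0.231 to -0.111, a hint from the data of a shared factor. Slide of the array as a block and a detection p as filter were not run, as the tables used give neither; the 95th percentile and all 9 arrays were used for the latter.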

Other observations

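The tests of histone genes and of the second array of replicate 1 were chosen after the values were seen, the test of neighbouring genes before. Histone genes stood among the highest changes in X376R, and 18 of 41 tested rose and 1 fell, with a median of 0.20. Between the resistant lines 16 were higher in X376R and 0 lower, and in PF1066R 6 rose and 1 fell. More cells in S phase could raise them. The proliferation and mitosis list had a median of 0.17 ± 0.0653 (error from resampling its genes), below that of the histone genes by less than its error. The DNA replication list had a median of 0.65. The values do not decide, and more cells in S phase and a change in histone transcription cannot be told apart for the histone genes.

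Neighbouring genes changed together more than shuffled gene orders give. Over 25 neighbouring tested genes the most extreme median in either direction was -0.312 in PF1066R, with a permutation p of 0.022 from 1000 shuffled gene orders. In X376R that median was -0.452, with a permutation p of 0.00599. PF1066R had 2 runs past the shuffles' limit and X376R 10. In X376R the longest run, from GPCPD1 to CST2, spanned 53 tested genes with a median of -0.34, of which 43 lay on that side and 26 passed, and the run from C20orf96 to PCED1A spanned 29 genes with a median of -0.33, 26 of them on that side. The run from FAM167A to XPO7 had a median of -0.43 over 25 genes, and that from TFIP11-DT to MTMR3 a median of 0.43 over 25. Gene order is that of the GRCh38.p14 table. A change of copy number in these segments is a hypothesis that may account for the runs, and shared regulation of neighbours is another. DNA was not measured, so neither was tested.

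The deposited log2 values of replicate 1 seem to be means of 2 arrays, and on that reading a second array can be worked out from them. This is inferred from the values, with 95.1%, 94.7% and 94.8% of them within 1e-06 of such a mean and a largest gap of 0.00079, and the RNA of such a second array is not given in the sources used here. It correlated with the first at r of 0.988, 0.991 and 0.989 in Parental, PF1066R and X376R. The spread between these 2 arrays was 0.125 in Parental, against 0.117, 0.119 and 0.132 between arrays of different replicate numbers. It was 0.114 in PF1066R, against 0.127, 0.132 and 0.144, and 0.127 in X376R, against 0.143, 0.151 and 0.158. How much of the spread between replicates is technical stays open.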
